A study of Penicillium oxalicum with 6 samples.

How the data were processed

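Ribosome profiling (Ribo-seq), which sequences the stretches of mRNA that ribosomes shield from nuclease, was carried out on mycelia of the filamentous fungus Penicillium oxalicum. The 6 libraries came from the wild type (n = 3) and from a strain with the gene PoxTMA7 knocked out (n = 3), and the labels call the libraries of each strain biological replicates. Per the labels' protocols, mycelia were grown in liquid medium with 1% glucose for 24 h and moved to medium with 1% Avicel, a microcrystalline cellulose, for 24 h. Lysates were digested with RNase I for 1 h, and RNA fragments of 26 to 34 nucleotides were cut from a gel for the libraries. Groups were taken from the sample titles. The genotype field of knockout replicates 2 and 3 gives PoxTMA8 and PoxTMA9 in place of PoxTMA7, whereas their titles and the series title name PoxTMA7. No RNA-seq libraries of the same mycelia were analysed here, so the values are footprint levels and no translational efficiency was computed.

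Each library has a deposited table of FPKM per gene, named so in its header, for the same 8909 identifiers in all 6 libraries. The submitters' processing notes name cutadapt, Bowtie, STAR 2.7 and DESeq2, with no role or order. The genome build, the annotation and the program that counted footprints are not given in the sources used here. The deposited FPKM of a wild-type library and of the knockout library of the same number summed to 2000000 within 0.44, while sums over other pairs missed that value by 502 to 2674. The normalization behind this is not given in the sources used here. The mean wild-type total was 1.047 times the mean knockout total, a log2 difference of 0.066 that enters every comparison at the deposited scaling.

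The depth of the libraries was read from the steps between FPKM values, since the FPKM of a gene is a whole number of footprints times a step for the library and a step for the gene. All 7855 genes above 0 in at least 3 libraries had whole numbers of footprints in all 6 libraries, within at most 0.2 of a footprint. When values were shuffled between genes, 134 of 1000 genes also did, against 1000 of the same 1000 unshuffled. On simulated data built with the estimated steps, 97.56% of 7676 genes were read back exactly. The library steps were given to this test, so it checks the footprints per gene and not the depths. The gene step spread less between genes (2.57-fold from the 5th to the 95th percentile) than the protein-coding gene lengths of the reference table do (13.8-fold). What the authors divided by is therefore not known, and FPKM was compared between libraries within a gene. Where genes are grouped by mean FPKM, that mean orders them only roughly by abundance.

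The tests planned before the data were examined assumed counts. As the deposited unit is FPKM, the planned fallback for normalized values was used, limma with a mean-variance trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The filter, an FPKM of at least 1 in at least 3 libraries, was chosen after the unit was known and kept 7703 genes. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values. A set of simulated libraries at the recovered depths, with a replicate CV of 4.2% beyond counting error, was run through the same test over 7855 genes. It called 98.5% of genes changed 4-fold, 64.2% of those changed 2-fold and 29.9% of those changed 1.5-fold, and 3 of 7474 unchanged genes. Only genes above a minimum mean number of footprints were changed, so the shares called do not cover genes with fewer. The simulated spread is 1 CV for all genes, from the median over genes with more footprints in these libraries. A median of estimates from 3 replicates tends to be low. The simulated libraries may therefore vary less than the real ones, which would make these shares and false calls too favourable. The p-values cover the spread between the 3 replicates of each strain only.

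The identifiers matched 0 of the 9964 locus tags in the given RefSeq table, and neither the files nor that table pairs them with gene names. PoxTMA7 itself and the 26 gene lists fixed before the data were examined were therefore not analysed here. The rule for named genes, for identifiers without annotation, was the 2 that rose most and the 2 that fell most by log2 fold change among genes past the threshold whose groups did not overlap. Alternatives fixed beforehand were a replicate block, leaving out each replicate, scaling by the median ratio, the upper quartile or the total, no filter, a mean of at least 50 footprints, limma-voom on recovered footprints, leaving out the 20 most abundant genes, and a pseudocount of 0.1. Alternatives added after the data were seen were a pseudocount of 5, a mean FPKM of at least 10, footprints thinned at random to the shallowest library, and leaving out each replicate with the filter set to the size of the smaller group. DESeq2 and the gene-list alternatives were not run. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.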

Results

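Footprint levels were measured in mycelia of Penicillium oxalicum on Avicel, in 3 libraries of the wild type and 3 of the PoxTMA7 knockout. TMA7 is known from yeast as a protein associated with the translation machinery, and the comparison asks how footprint levels per gene differ when its P. oxalicum counterpart is lost. The wild-type libraries held 701702, 858542 and 437902 recovered footprints in replicates 1, 2 and 3. The knockout libraries held 1168893, 1297990 and 1452428. Every knockout library held at least 1.36 times the recovered footprints of every wild-type library, so depth and genotype go together in this design. The median gene had 13 footprints in the shallowest library and 40 in the deepest, for which counting error alone gives a CV of 27.7% and 15.8%. Across genes, log2(FPKM + 1) correlated at 0.952 to 0.971 between libraries of 1 genotype and at 0.867 to 0.876 between genotypes. Pairs of replicates differed by more than counting error, with a chi-square per degree of freedom of 1.6 to 2.46, so no library was a copy of another.

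Footprint levels of 2996 genes differed between the strains, 38.9% of the 7703 tested (limma, adjusted p under 0.05). Of these, 1288 were higher and 1708 lower in the knockout. A change of at least 2-fold was seen in 1631 of them, 691 higher and 940 lower. With only genes of a mean of at least 50 footprints per library tested, 1865 genes passed the threshold, 673 of them with a 2-fold change. At the main settings, large changes were mostly falls, with 127 genes at least 16-fold lower and 23 at least 16-fold higher. The pseudocount of 1 holds down the fold of genes near 0 in 1 strain, and these 2 counts were not made with another. Falls made up 57.0% of the changed genes at the deposited scaling and 48.5% with upper-quartile scaling, so the direction of the majority depends on the scaling. Upper-quartile scaling moved the median log2 change of tested genes by 0.11, from -0.047 to 0.064. The values of the strains did not overlap for 3804 genes, 49.4% of those tested, where chance gives 10% for 3 against 3. Of these 3804 genes, 2927 were past the threshold. In all, 4707 of the tested genes did not pass it, and the median standard error of a log2 change was 0.275.

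**Figure D1:**
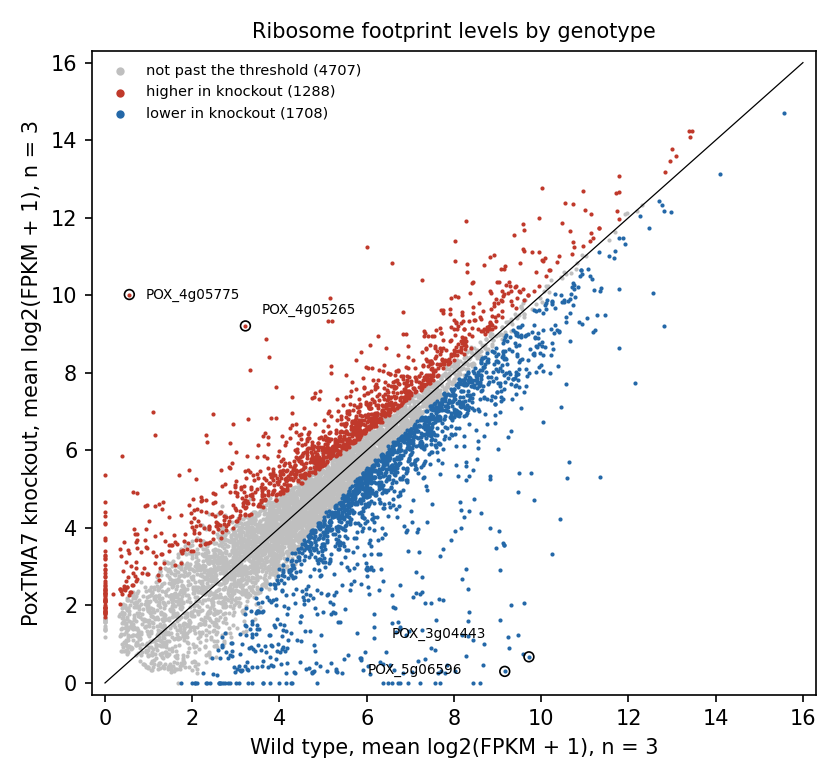
Mean log2(FPKM + 1) of each tested gene in the wild type (x axis, n = 3) and the PoxTMA7 knockout (y axis, n = 3), with genes past the limma threshold in red (1288 higher) and blue (1708 lower) and the others in grey. The black line marks equal levels. The 4 circled genes are the 2 that rose most and the 2 that fell most by log2 change on this scale.

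The gene that rose most, POX_4g05775, had an FPKM of 0, 0 and 2.19 in the wild-type libraries and of 1025, 1005 and 1080 in the knockout libraries. Its fitted log2 change was 9.46 with a standard error of 0.37 (limma, adjusted p = 2.66e-10). It depends on the pseudocount, at 11.83 with 0.1 and 7.53 with 5. The wild-type value rests on 1 footprint against 4446 in the knockout, a depth-corrected ratio of 2158 with a 95% exact counting interval of 387 to 85274. POX_4g05265 rose from an FPKM of 8.93 ± 4.6 to 591 ± 21.6 (SD, n = 3 each), a log2 change of 5.99 with a standard error of 0.25 (limma, adjusted p = 4.24e-10). The gene that fell most by fitted log2 change, POX_3g04443, had an FPKM of 842, 812 and 872 in the wild type and of 0, 1.46 and 0.65 in the knockout. Its log2 change was -9.05 with a standard error of 0.29 (limma, adjusted p = 5.30e-11), from 1676 footprints against 3. The depth-corrected wild-type over knockout ratio was 1151, with a 95% exact counting interval of 393 to 5586. POX_5g06596 had an FPKM of 565, 618 and 538 in the wild type and of 0, 0 and 0.86 in the knockout. Its log2 change was -8.87 with a standard error of 0.29 (limma, adjusted p = 5.80e-11). Its knockout value is 1 footprint against 886, a ratio of 1825 with a 95% exact counting interval of 327 to 72163. These intervals cover counting error only. Those of POX_3g04443 and POX_5g06596 overlap, and with a pseudocount of 0.1 their log2 changes were -10.75 and -11.40. The order of these 2 therefore depends on the settings. The named genes were picked with a pseudocount of 1. A smaller one enlarges the changes of genes at 0 in 1 strain most, so other genes could then rank above named ones, POX_4g05265 included. The files do not pair the identifiers with gene names, so what the named genes encode was not analysed here.

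Genes with higher levels passed the threshold more often. Of the 143 genes with a mean FPKM of at least 1000, 60 were higher and 62 lower in the knockout, 85.3% in all. Of the 1462 genes from 100 to 1000, 420 were higher and 604 lower (70.0%). Of the 4395 genes from 10 to 100, 659 were higher and 907 lower (35.6%). Of the 1703 genes below 10, 149 were higher and 135 lower (16.7%), and the median count in this last group was 3 footprints per library. Counts below 10 FPKM depend on the settings. Leaving out any 1 knockout replicate turned the balance to falls, with 36 or 37 genes higher and 104 to 108 lower at the filter of 3 libraries, and 96 to 98 higher and 116 to 118 lower with the filter at the size of the smaller group. Leaving out wild-type replicate 2 at the filter of 3 libraries gave 89 that were lower. It also turned with limma-voom on recovered footprints (96 higher, 192 lower), after thinning to the shallowest library (79 higher, 115 lower) and with a pseudocount of 5 (150 higher, 151 lower). From 10 to 100 FPKM, thinning gave 377 genes that were higher, leaving out knockout replicate 1 or 2 with the filter at the size of the smaller group gave 402 and 420, and a mean of at least 50 footprints gave 345 higher and 347 lower. Scaling turned the balance from 10 to 100 FPKM to rises, with 792 higher and 729 lower for the upper quartile, 768 and 758 for the median ratio, and 763 and 760 without the 20 most abundant genes. At 1000 FPKM and above, where the counts were close to even, upper-quartile scaling gave 65 higher and 52 lower, the median ratio 63 and 52, and library size 62 and 54. The median fold change of the genes past the threshold went the other way, from 4.52-fold below 10 FPKM to 1.72-fold at 1000 and above. Small changes of genes with few footprints were not detectable at this depth. The bounds of these groups were chosen after the data were seen.

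FPKM orders genes only roughly, because the authors' divisor per gene is not known. The most abundant gene of each library, not necessarily the same gene, took 4.72% ± 0.31 of all FPKM in the wild type and 2.71% ± 0.18 in the knockout (SD, n = 3 each). The 10 most abundant genes of each library took 13.6% ± 0.54 and 15.05% ± 0.43, and the 100 most abundant took 37.02% ± 0.55 and 40.98% ± 0.32. Each of these 3 differences had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows.

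Genes that fell by at least 2-fold lay next to each other in the identifier order more often than under random placement. Runs of at least 5 consecutive tested identifiers, all changed at least 2-fold in 1 direction and past the threshold, numbered 7 for falls and 1 for rises. With the filter kept at 3 libraries, which tests fewer of these genes once a library is left out, the number of runs of falls was 3 without wild-type replicate 1 and 4 without wild-type replicate 3. It was 6 and 7 with the filter at the size of the smaller group, where leaving out wild-type replicate 1 gave 2 runs of rises. A mean of at least 50 footprints gave 3 runs of falls and 2 of rises. The longest run of falls held 23 genes, POX_3g04443 among them. Their summed FPKM was 6935 ± 108.3 in the wild type and 25.0 ± 6.9 in the knockout (SD, n = 3 each), from 13388 and 104 footprints. Each gene of this run was at an FPKM of at least 29.8 in the wild type and at most 3.83 in the knockout, as group means. The tested genes just before and just after it had log2 changes of -0.21 and -0.43. Of the 3 tested genes on each side, 3 of the 6 were past the threshold, counting both directions, against 38.9% of all tested genes. The largest log2 change among the 6 was 2.41 in size. The second run of falls held 11 genes and went from a summed FPKM of 2349 ± 111.4 to 21.3 ± 6.4. A run of 7 with POX_5g06596 went from 4689 ± 316.9 to 190.6 ± 36.2. The other 4 runs of falls held 5 or 6 genes, and their knockout sums were between 0.6% and 7.59% of the wild-type sums. The run of rises held 7 genes and went from 1434 ± 32.8 to 4919 ± 81.7. In 1000 random orders of the tested genes, the longest run of falls was 8 genes and the highest number of such runs was 2. A run of rises of at least 7 genes was found in 1 of the 1000 orders, and it held 8 genes. The highest number of runs of rises in an order was 2, so the number observed, 1, was within the range of random orders. The longest run of rises was 5 genes after thinning, without wild-type replicate 2 and without knockout replicate 2, and 6 genes at a mean of at least 50 footprints. Runs of falls held 62 genes, 3.6% of all falls past the threshold, and 45 of the 127 genes that were at least 16-fold lower. This definition of a run was chosen after the data, and other definitions, had been looked at.

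**Figure D2:**
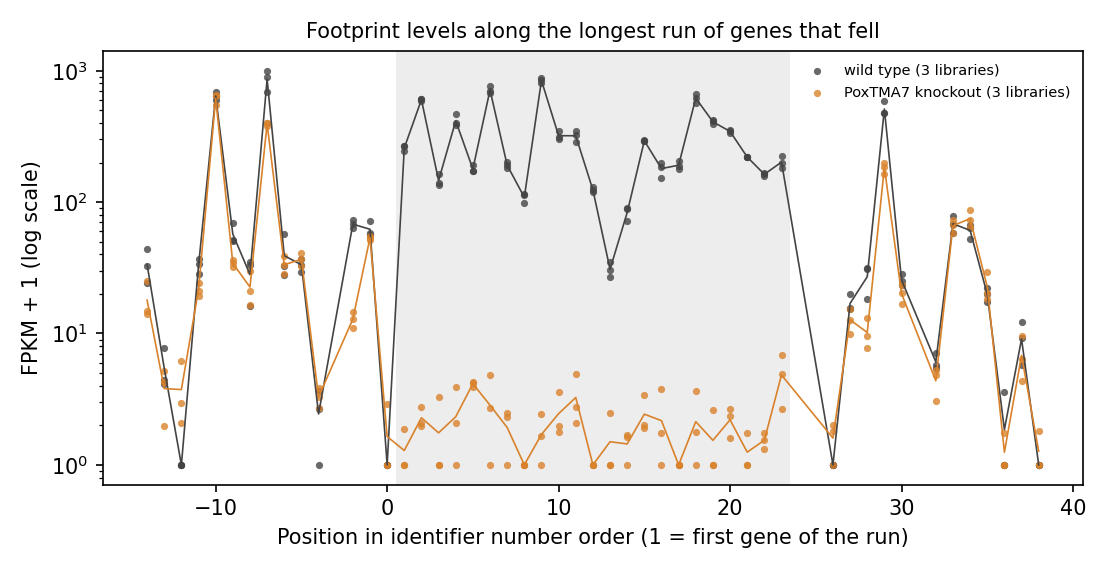
FPKM + 1 on a log axis for each library (points) and the mean of each strain (lines), along the identifier numbers around the longest run of falls, which is shaded. All 23 genes of the run lie far lower in the 3 knockout libraries, with a summed FPKM of 25.0 against 6935. Of the 6 tested genes nearest to its edges, 3 were past the threshold, counting both directions, against 38.9% of all tested genes.

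**Figure D3:**
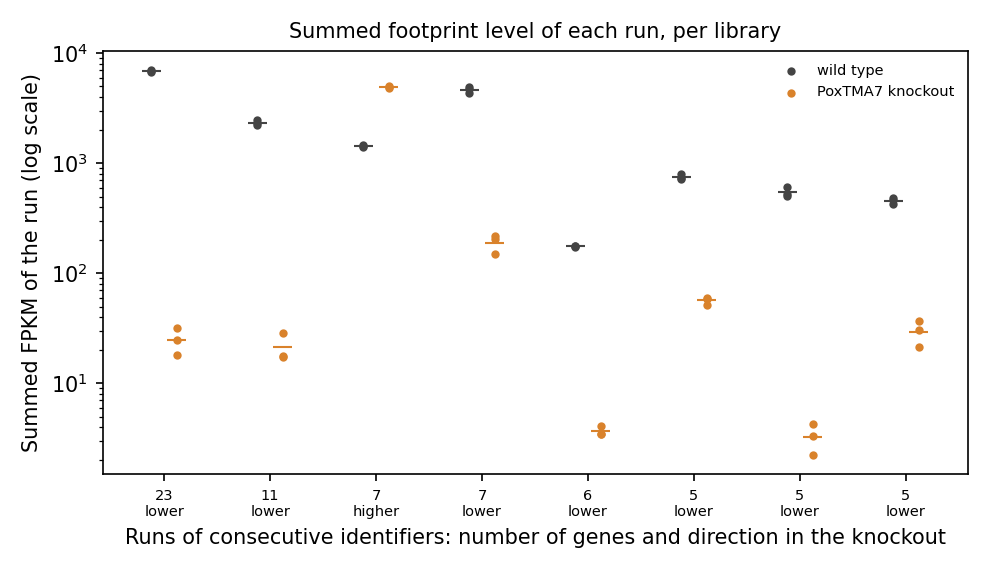
Summed FPKM (log axis) of each of the 8 runs in each library, with points for libraries and bars for the mean of each strain (n = 3). The 7 runs of falls, which were picked for their falls, keep between 0.36% and 7.59% of the wild-type sum.

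Genes listed at 0 in all libraries of 1 strain and above 0 in all libraries of the other were more often at 0 in the shallower wild type. There were 121 genes at 0 only in the wild type, with knockout means of up to 40.9 FPKM, 8 of them at 10 or more. There were 40 genes at 0 only in the knockout, with wild-type means of up to 387.7 FPKM, 20 of them at 10 or more and 8 at 100 or more. The number at 0 only in the wild type was 186 without wild-type replicate 1, 195 without wild-type replicate 2, 200 without knockout replicate 1 and 214 without knockout replicate 2. The number at 0 only in the knockout was 77 without knockout replicate 3. After footprints were thinned to the shallowest library, the numbers at 0 only in the wild type and only in the knockout were 56 and 107, so their order depends on depth.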

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

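No gene past the threshold at the main settings was past it in the opposite direction under any of the 24 alternatives run. These reuse the same libraries and could hardly turn a direction. Of the 2996 genes, 2714 were called the same way with upper-quartile scaling, 2760 with the median ratio and 2830 with library size. Limma-voom kept 2846 and thinning 2067. POX_3g04443, POX_4g05265 and POX_4g05775 passed under all 24, and POX_5g06596 under the 21 that tested it. Their log2 changes were -10.75 to -7.22, 5.47 to 6.34, 7.53 to 11.83 and -11.4 to -6.78, in that order. A mean of at least 50 footprints per library, which tests fewer genes, gave 1865 genes past the threshold (838 higher, 1027 lower), 673 of them with a 2-fold change. Thinning to the shallowest library, added after the data were seen, gave 2157 genes past the threshold, and 56 and 107 genes listed at 0 only in the wild type and only in the knockout. Over 100 further thinning draws these were 41 to 69 and 79 to 113.

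Leaving out 1 replicate at a time gave 2354 to 3002 genes past the threshold (925 to 1302 higher, 1414 to 1711 lower), 1418 to 1719 with a 2-fold change, and 155 to 214 and 44 to 77 genes at 0 only in the wild type and only in the knockout, where fewer libraries have to be at 0 or above 0. With the filter kept at 3 libraries, the longest run of falls held 16 genes without any 1 of the wild-type replicates, because 7 of its 23 genes were then not tested. With the filter at the size of the smaller group, which was added after that shorter run had been seen, it held 23. The replicate block gave 3134 genes past the threshold. Deviations of same-numbered libraries correlated at 0.024, 0.029 and 0.133 across 4820 genes, and 2 of 6 libraries correlated best with their own number, so the number is not taken to pair libraries. DESeq2, the gene-list alternatives and the level of PoxTMA7 were not run.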

Other observations

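The tests of the scaling and, for the run, of depth, random placement and a missing stretch were chosen only after the result was seen. The thinning tests of the other patterns and the other splits of the libraries were set before their results.

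More genes fell than rose, 57.0% of those past the threshold. The excess depends on the scaling: falls made up 52.4% with scaling by the total, 50.1% with the median ratio and 48.5% with the upper quartile. Centring on the median ratio largely sets an even split, and which scaling is right is not known. Whether the deposited scaling made the excess or the others removed a real one cannot be told apart. The difference in depth is argued against as the cause, because thinning all libraries to the shallowest at the deposited scaling left 60% falls. A difference between genotypes in the total number of footprints per cell stays open and was not tested, since the deposited totals carry no outside standard.

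More genes were listed at 0 only in the wild type than only in the knockout, 121 against 40. The greater depth of the knockout libraries is a candidate explanation, since after thinning the numbers were 56 and 107. An effect of the genotype on genes at very low levels was not tested separately.

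The run of 23 consecutive identifiers that fell was weighed against 3 explanations. The difference in library depth is argued against by the footprints of the run, 104 in the deeper knockout libraries against 13388 in the wild type. After thinning the longest run of falls still held 23 genes, against 8 over random orders of the unthinned genes. Thinning takes mostly knockout footprints, so it could hardly have ended a fall in the knockout and does not decide this. Random placement of changed genes is argued against by 0 of 1000 random orders holding a run as long, and the log2 changes of neighbouring identifiers correlated at 0.236 across genes, against at most 0.035 in those orders. A stretch of the genome missing from the knockout strain cannot be told apart from a loss of expression: the pooled knockout level was 0.36% of the wild-type level, which stray or shared reads could give, and no DNA was analysed here. A direct or indirect effect of losing PoxTMA7 stays open as well, untested, as does whether consecutive numbers are neighbours on a chromosome.

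The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2996 genes past the threshold, 1631 of them with a 2-fold change, and was the only 1 of the 10 with counts that large. The highest of the other splits gave 0 for both with limma, with at most 128 genes at an unadjusted p under 0.05 against 3589 in the real split. Each of those other splits puts libraries of both strains on each side. The difference between strains then adds to the spread within sides and lowers the counts, so they are no baseline for chance.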
